A study of Saccharomyces cerevisiae with 7 samples.

How the data were processed

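The series holds total RNA of 7 Saccharomyces cerevisiae samples, labelled with biotin and hybridised one per array to an Affymetrix array that also carries probe sets for fission yeast. The 3 genotypes are wild type (3 samples), ssn6 deletion (2) and tup1 deletion (2), taken from the labels. The labels do not say that the replicates come from separate cultures, so the p-values measure the spread between these samples, which may be technical. Pairs of arrays held exactly the same value for at most 1 of 5449 genes, and replicate arrays of a genotype differed by a standard deviation of 0.197 to 0.498 over genes.

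The deposited values are log2 expression values per probe set, normalized between arrays by the authors. RMA and limma are named, without role or version, per the submitters' processing notes. The values span 2.76 to 14.65. RMA values carry no detection call, and summarised log2 values compress fold changes of dim genes, so background was judged from the fission yeast probe sets. As usually run, RMA includes quantile normalization, which assumes that most genes do not change between arrays. Of 10928 probe sets, 5498 have 1 budding yeast gene, 1 has several genes, 1746 belong to fission yeast and 3683 have no gene in the table used. Of these unnamed ones, 166 are Affymetrix controls, 47 are labelled as reporter sequences and 3470 are others. Gene symbols come from the platform annotation, with 12 updated through a table of assembly R64, which served only for names and gene order.

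The tests ran on 5449 genes. For 47 genes with several probe sets the one with the highest mean over all arrays was used. One linear model with a mean per genotype was fitted to all 7 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 4 residual and 3.19 prior degrees of freedom), since 2 arrays per deletion leave few degrees of freedom on their own. The tests were two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Fold changes are differences of mean log2 values with their moderated standard errors; the median standard error was 0.18 against wild type and 0.20 between the deletions. The floor of an array is the 95th percentile of its fission yeast probe sets. A gene under the floor on every array of one group has only a bound there, given as at least N-fold against the higher of the floor and its own value per array.

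The 31 gene lists, the tests and most of the alternatives were fixed before the data were examined. Lists were tested with camera, at the preset correlation of 0.01 and with an estimated correlation, and with fry, adjusted over the lists of a comparison. An estimated correlation rests on 4 residual degrees of freedom. The subtelomeric list holds the 10 outermost protein-coding genes of each chromosome arm by gene order. The rule for named genes took CYC8 and TUP1, the 12 largest rises and 8 largest falls per deletion among genes past the threshold whose arrays do not overlap with wild type, up to 4 members with the largest change per list, and the 8 largest differences of each sign between the deletions. Other names were chosen after the values were seen or are members of a list that are given for contrast.

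Both deletions were set against the same wild-type arrays, so chance overlap was simulated with 100 draws of all 7 arrays without any change. In each draw both unchanged groups were set against the same drawn wild-type arrays, and a gene had the same spread on all arrays. The overlap of independent lists was computed as the product of list sizes over the genes tested. The procedure was tested on simulated data, 20 tables of 5449 genes with 200 changed ones. At log2 changes of 0.5, 1 and 2 it recovered 7.31%, 75.6% and 98.9% for ssn6 against wild type, 5.60%, 74.5% and 99.1% for tup1, and 5.52%, 64.7% and 98.0% between the deletions. False calls made up 5.81%, 4.99% and 4.53%. A list of 20 genes shifted by 0.5 was called in 20 of 20 tables, and 2, 1 and 1 of 600 unshifted lists were called. The simulated genes varied independently and with the same spread on all arrays, so these rates do not hold for lists with correlated members. In the data the estimated correlation was 0.84 for ribosomal protein genes and 0.75 for ribosome biogenesis genes.

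The alternatives were quantile normalization of the table, median centring, a filter at the floor, eBayes with trend and robust settings, only the genotypes compared, array weights, the replicate number as a block, the mean of a gene's probe sets, an adjusted p of 0.01, and leaving out each array in turn, where a lone array is assumed to vary like the other groups. A crossed block, and leaving out wild-type replicate 2 with tup1 replicate 1, were chosen after seeing the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.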

Results

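RNA abundance was measured in 7 samples of budding yeast, Saccharomyces cerevisiae, on a one-colour Affymetrix array. There were 3 wild-type samples, 2 lacking SSN6 and 2 lacking TUP1, all in the haploid laboratory strain BY4742, which is of the alpha mating type. Ssn6 (gene CYC8) and Tup1 (gene TUP1) are subunits of one corepressor complex, which is brought to promoters by DNA-binding repressors. Cells were grown to an OD600 of 0.8 in 200 mL of rich medium with 2% glucose, per the labels. The series title names the regulation of transcription by this corepressor, and each deletion was set against wild type and against the other deletion for 5449 genes. The series' design text speaks of duplicates, while the labels list 3 wild-type samples, and all 3 were used.

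Signal stood well above background for most genes. The median log2 level of the tested genes lay between 10.95 and 11.06 on the 7 arrays. The background floor, taken from 1746 probe sets for fission yeast genes on the same array, lay between 5.50 and 5.67, and 36 to 70 genes per array fell under it. The ssn6 arrays resembled each other most, with a standard deviation of their differences over genes of 0.197, against 0.367 to 0.498 for pairs of wild-type arrays and 0.409 for the tup1 pair. Wild-type replicate 2 stood apart in the actin control, whose 3' probe set read 2.85 log2 units above the 5' one, against 0.52 to 0.92 on the other 6 arrays. The number of arrays, 2 or 3 per genotype, limits the precision of every value that follows.

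The deleted genes were low where the labels place the deletions. CYC8 (YBR112C) had log2 levels of 11.22, 11.32 and 11.24 in wild type, 11.56 and 11.43 in the tup1 deletion, and 5.62 and 6.07 in the ssn6 deletion, a fall of −5.42 ± 0.16 (SE, adjusted p = 3.31e-06). TUP1 (YCR084C) stood at 12.50, 11.56 and 12.19 in wild type and at 11.81 and 11.90 in the ssn6 deletion. In the tup1 deletion it read 4.69 and 5.07, under the floor on both arrays, which makes it at least 92.7-fold lower than in wild type (adjusted p = 9.61e-06). Neither gene differed past the threshold in the other deletion (TUP1 −0.22 ± 0.27 in ssn6, adjusted p = 0.588; CYC8 0.24 ± 0.16 in tup1, adjusted p = 0.327). Whether these probe sets lie in the deleted part is not given in the sources used here. Of the strain's marker genes, LYS2 (mean log2 level 4.57 to 4.61 per genotype) and URA3 (3.70 to 3.81) were under the floor, LEU2 (5.63 to 5.67) lay at it, and HIS3 read 12.01 to 12.52. No marker passed the test in either deletion, the lowest adjusted p being 0.119 for HIS3 in tup1.

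Loss of Ssn6 raised genes that glucose-grown alpha cells keep low, some of them over 50-fold. The sugar transporter gene HXT13 rose 243-fold (log2 7.93 ± 0.15, adjusted p = 6.19e-07), the anaerobic cell wall gene DAN1 86.7-fold (6.44 ± 0.17) and DAK2, a dihydroxyacetone kinase gene, 82.5-fold (6.37 ± 0.15). DIT1 and DIT2, which make the dityrosine of the spore wall, rose by 5.81 ± 0.18 and 5.51 ± 0.20. Falls were smaller: after CYC8 itself, ARO10, a decarboxylase gene of aromatic amino acid breakdown, fell by 3.60 ± 0.25 (adjusted p = 0.000107), and the Ty element gene YBL100W-A by 2.26 ± 0.17, while IMD2, an IMP dehydrogenase gene, was 5.65-fold lower (adjusted p = 0.00157). In all, 1059 of 5449 genes passed an adjusted p of 0.05, 500 higher and 559 lower than wild type (n = 2 and 3 arrays). Which direction held the majority was not stable. After median centring 536 genes were higher and 439 lower, and rises also outnumbered falls without wild-type replicate 1 (419 and 351) or 3 (473 and 464) and without ssn6 replicate 1 (220 and 78) or 2 (227 and 52), while array weights gave 786 and 1353.

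Among genes that changed at least 2-fold in the ssn6 deletion, rises outnumbered falls, with 326 higher and 138 lower. The 326 risen genes had a median wild-type level of 9.43, against array medians of 10.95 to 11.06 for all genes, and 2 of them were under the floor in wild type. Changes of 16-fold or more numbered 41 rises and 1 fall. Of 31 gene lists, 21 passed limma's camera test with its preset correlation between genes, 18 upward and 3 downward, and 20 passed fry, which tests each list by itself. With a correlation estimated from the arrays, 0 lists passed camera, the lowest adjusted p being 0.0522, and 8 lists had an unadjusted p under 0.05.

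Genes of the opposite mating type came on in the ssn6 deletion. All 7 a-specific genes rose (7 adjusted over the list alone), with a median of 4.05 (camera adjusted p = 1.33e-11, and adjusted p = 0.0522 with an estimated correlation). The a-factor gene MFA2 rose by 5.45 ± 0.22, AGA2, the binding subunit of a-agglutinin, by 5.12 ± 0.19, and STE2, the receptor for alpha-factor, by 4.05 ± 0.18. Of the 5 alpha-specific genes, 2 fell (2 adjusted over the list alone) and 3 did not pass, with a median of −0.55 (adjusted p = 0.0331, and adjusted p = 0.348 with an estimated correlation). STE3, the receptor for a-factor, fell by 1.97 ± 0.14 (adjusted p = 0.000128). The alpha-factor gene MF(ALPHA)2 read −0.55 ± 0.14 (adjusted p = 0.0341), a call lost after median centring and without wild-type replicate 1 or 3 or either ssn6 array (adjusted p up to 0.236). The alpha-specific list no longer passed without wild-type replicate 1 (adjusted p = 0.057), wild-type replicate 3 (0.0798) or ssn6 replicate 1 (0.0632), nor with the replicate number as a block (0.0758) or crossed (0.0857). Among 11 genes expressed in haploids of both mating types, 2 rose and 0 fell (2 and 1 adjusted over the list alone), and the list did not pass (adjusted p = 0.299, and adjusted p = 0.425 with an estimated correlation).

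In 3 groups of cell surface genes, all measured members rose in the ssn6 deletion. All 4 measured flocculin genes, which encode adhesins, rose (4 adjusted over the list alone, median 3.88, adjusted p = 4.09e-08, and adjusted p = 0.102 with an estimated correlation), among them FLO11 by 4.92 ± 0.16 and FLO1 by 4.49 ± 0.31. The 6 measured DAN and TIR genes, for mannoproteins of anaerobic cell walls, rose too (6 adjusted over the list alone, median 3.22, adjusted p = 2.49e-09, and adjusted p = 0.0522 with an estimated correlation), TIR2 by 3.88 ± 0.24. All 13 measured seripauperin (PAU) genes rose (13 adjusted over the list alone, median 3.90, adjusted p = 2.24e-17, and adjusted p = 0.0522 with an estimated correlation), PAU24 by 5.69 ± 0.13 and PAU3 by 4.86 ± 0.31. Members of the FLO, PAU, MAL, IMA and HXT families are close in sequence, so probe sets can take signal from a relative. Of 8 other genes regulated by oxygen, among them the repressor gene ROX1, 2 rose and 6 did not pass (2 adjusted over the list alone, adjusted p = 0.0195, 0.0511 by fry, and adjusted p = 0.34 with an estimated correlation).

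Some genes for sugar transport and for carbon sources other than glucose rose in the ssn6 deletion. Of 14 hexose transporter genes, 7 rose and 7 did not pass (7 adjusted over the list alone, median 1.28, adjusted p = 1.38e-08, and adjusted p = 0.0813 with an estimated correlation). HXT17 rose by 6.41 ± 0.22 and HXT8 by 3.39 ± 0.22, while HXT1 (0.28 ± 0.33), HXT3 (0.14 ± 0.18) and HXT7 (0.20 ± 0.13), transporters of glucose-grown cells or of low glucose, did not pass. Of 9 maltose and isomaltase genes, 7 rose (9 adjusted over the list alone, median 2.29, adjusted p = 9.8e-10, and adjusted p = 0.0522 with an estimated correlation), the isomaltase gene IMA1 by 4.54 ± 0.14 and the maltase gene MAL32 by 4.18 ± 0.16. Among 17 genes for invertase, gluconeogenesis and the use of ethanol, acetate and glycerol, 4 rose and 13 did not pass (5 adjusted over the list alone, median 0.69, adjusted p = 3.11e-05, and adjusted p = 0.35 with an estimated correlation). The mean of this list was 10.82 in wild-type replicate 3 and 11.45 and 11.47 in the other wild-type arrays. The 4 risen genes were ADH2 (2.81 ± 0.19), PCK1 (2.39 ± 0.16), SUC2 (1.39 ± 0.18) and GUT1 (1.36 ± 0.19). With array weights 8 of the 17 rose and 1 fell. Galactose genes gave 3 rises of 9 (4 adjusted over the list alone, adjusted p = 0.00399, and adjusted p = 0.249 with an estimated correlation), with 1 rise left without wild-type replicate 1 or 3 and 0 without ssn6 replicate 1 or 2.

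Of 13 peroxisomal fatty acid oxidation genes, 10 rose in the ssn6 deletion (12 adjusted over the list alone, median 1.80, adjusted p = 3.56e-09, and adjusted p = 0.266 with an estimated correlation). The catalase gene CTA1 rose by 3.13 ± 0.39 and the reductase gene SPS19 by 2.63 ± 0.19. Without either ssn6 array 5 of these genes passed. Their mean level was 9.82 in wild-type replicate 3, against 10.65 and 10.52 in the other wild-type arrays and 11.96 and 11.94 in ssn6. Respiratory chain genes moved little, with 1 rise among 35 (0 adjusted over the list alone) and a median of 0.23, yet passed as a list (adjusted p = 3.11e-05, and adjusted p = 0.249 with an estimated correlation). Glycolysis genes had 0 changes among 15 (0 adjusted over the list alone, adjusted p = 0.621), and 2 of 11 citric acid cycle genes rose (2 higher and 1 lower adjusted over the list alone, adjusted p = 0.264).

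Genes of sporulation and stress moved in part. Of 16 middle and late sporulation genes, 4 rose and 12 did not pass (4 adjusted over the list alone, adjusted p = 0.0125, and adjusted p = 0.35 with an estimated correlation), DIT1, DIT2, SPS4 (3.28 ± 0.23) and the glucoamylase gene SGA1 (2.42 ± 0.15). Of 19 early meiotic genes, 4 rose and 1 fell (the same counts adjusted over the list alone, adjusted p = 0.0369, and adjusted p = 0.35 with an estimated correlation), with IME1, the inducer of meiosis, up by 2.46 ± 0.28 and the meiotic chromosome gene HOP1 by 1.31 ± 0.18. Of the early meiotic genes 2 rises and 0 falls were left without ssn6 replicate 1. The sporulation list missed the threshold without wild-type replicate 1 (adjusted p = 0.0645) or ssn6 replicate 1 (0.0814), and the meiotic list without wild-type replicate 1 (0.0859), wild-type replicate 3 (0.0623) or ssn6 replicate 1 (0.14). The meiotic list also missed it with quantile normalization (0.0744), with the replicate number as a block (0.0503), with that number crossed (0.0857) and by fry (0.0767), so its call is weak. Among 20 general stress genes, 4 rose and 2 fell (6 and 2 adjusted over the list alone, adjusted p = 0.0336, and adjusted p = 0.35 with an estimated correlation), GAC1, for a phosphatase subunit in glycogen synthesis, rising by 2.19 ± 0.17 and the heat shock gene SSA4 falling by 1.04 ± 0.13. The stress list missed it without wild-type replicate 2 (0.0589) or ssn6 replicate 2 (0.0636) and with quantile normalization (0.0746). The 4 rises became 2 without wild-type replicate 1 and 1 without either ssn6 array, and 1 fall was left in each case. In the ribonucleotide reductase and damage list, 3 of 5 rose (4 adjusted over the list alone, adjusted p = 8.73e-05, and adjusted p = 0.123 with an estimated correlation), HUG1 by 3.77 ± 0.22 and RNR3 by 2.85 ± 0.13.

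Of the 16 genes for DNA-binding repressors, most of them known to recruit the complex, 9 rose and 7 did not pass in the ssn6 deletion (10 adjusted over the list alone, median 0.77, adjusted p = 8.39e-07, and adjusted p = 0.172 with an estimated correlation). SUT1 rose by 2.21 ± 0.19, MIG3 by 2.15 ± 0.17 and CIN5 by 1.97 ± 0.20, and without ssn6 replicate 2 the count was 5. Nitrogen-regulated genes gave 7 rises and 2 falls of 20 (9 and 2 adjusted over the list alone, adjusted p = 0.00457, and adjusted p = 0.394 with an estimated correlation), with the amino acid permease gene GAP1 up by 2.32 ± 0.13 and the allantoin permease gene DAL4 by 1.62 ± 0.12. The 7 rises were 4 without wild-type replicate 3 and 2 without either ssn6 array, with 0 falls left without either. Subtelomeric genes, the 10 outermost per chromosome arm, gave 89 rises and 15 falls of 235 (99 and 30 adjusted over the list alone, median 0.41, adjusted p = 4.22e-14, and adjusted p = 0.0522 with an estimated correlation), or 59 rises and 6 falls without ssn6 replicate 1 and 60 and 4 without ssn6 replicate 2. This set shares 49 members with the other lists, among them all 9 maltose genes and 8 of the PAU genes. VBA3, a vacuolar amino acid permease gene near a chromosome end, rose by 6.42 ± 0.47.

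Lists that passed downward in the ssn6 deletion were the phosphate genes and ribosome biogenesis, beside the alpha-specific genes. Of 10 phosphate genes, 5 fell and 1 rose (7 and 1 adjusted over the list alone, median −0.68, adjusted p = 0.0118, and adjusted p = 0.298 with an estimated correlation), VTC4 of the polyphosphate polymerase by 0.63 ± 0.12, and 1 fell and 0 rose without either ssn6 array. Ribosome biogenesis genes had a median of −0.58, and 6 of 54 fell (1 adjusted over the list alone, adjusted p = 0.000538, and adjusted p = 0.621 with an estimated correlation, with 0.188 by fry). That count was 1 without wild-type replicate 1, 0 without either ssn6 array and 22 without either tup1 array. The rRNA control probe sets had means of 8.73 and 7.47 on the ssn6 arrays, against 11.06, 8.41 and 12.42 in wild type. Among 128 ribosomal protein genes 2 rose and 0 fell (0 adjusted over the list alone), with a median of −0.05 while the test leaned upward against the other genes (adjusted p = 0.57). Iron genes gave 3 rises and 3 falls of 16 (4 and 3 adjusted over the list alone, adjusted p = 0.0841), counts of which 0 rises and 0 falls remained without ssn6 replicate 1 and 1 rise and 0 falls without ssn6 replicate 2. Amino acid genes under Gcn4 gave 3 falls of 21 (3 adjusted over the list alone, adjusted p = 0.147), 1 without wild-type replicate 1, 5 without wild-type replicate 2 and 0 without either ssn6 array. Osmotic genes gave 2 rises of 11 (2 adjusted over the list alone, adjusted p = 0.0552), histone genes 1 fall of 8 (1 adjusted over the list alone, adjusted p = 0.475) and COS genes 0 changes of 8 (0 adjusted over the list alone, adjusted p = 0.737). Without wild-type replicate 1 the osmotic list (adjusted p = 0.0296) and the iron list (0.0414) passed, the osmotic list also after median centring (0.0444), and by fry the Gcn4 list (0.0289) and the histone list (0.0243).

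The number of genes called in the ssn6 deletion rested on having both of its arrays, since 298 genes passed without ssn6 replicate 1 and 279 without replicate 2, of which 293 and 274 changed at least 2-fold. With array weights, which favour the ssn6 arrays, 2139 genes passed, and at an adjusted p of 0.01 the count was 397.

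**Figure D1:**
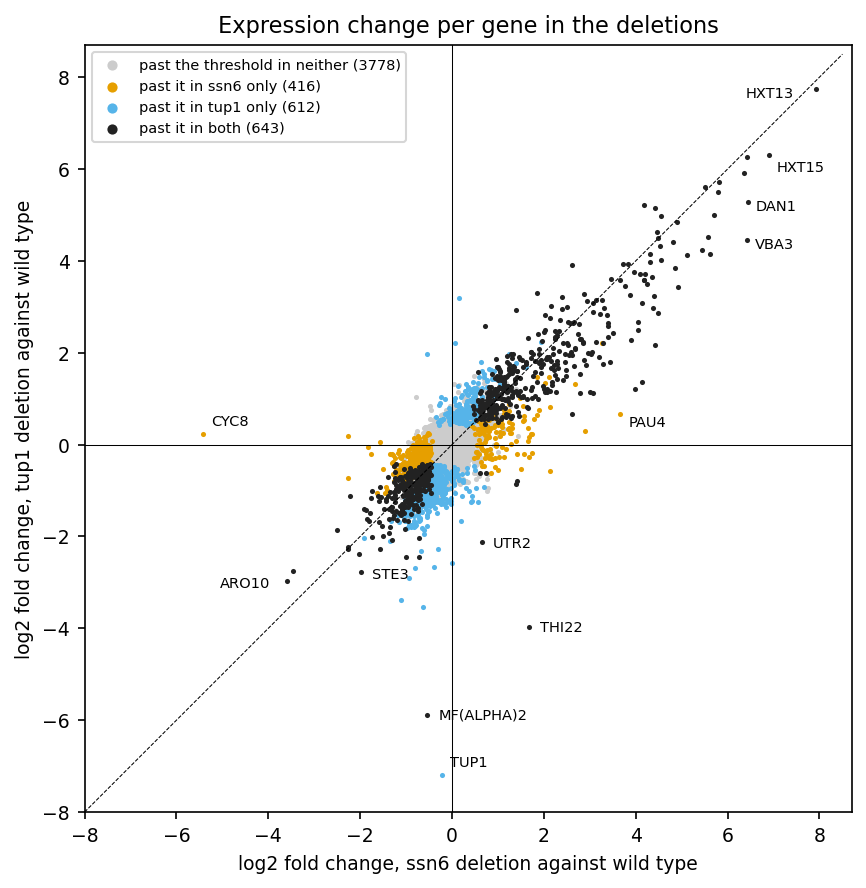
Log2 fold change of each of 5449 genes in the ssn6 deletion (x axis) and the tup1 deletion (y axis), each against the same 3 wild-type arrays; one point per gene, coloured by the comparisons in which it passed an adjusted p of 0.05 (416 genes in ssn6 only, 612 in tup1 only, 643 in both), with the diagonal dashed. HXT13 lies farthest up, at 7.93 and 7.75, while MF(ALPHA)2, THI22 and UTR2 lie far below it.

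Loss of Tup1 also raised sugar transporter and other genes, and it lowered genes of the cells' own mating type. HXT13 rose 215-fold (log2 7.75 ± 0.15, adjusted p = 7.3e-07), HXT17 76.9-fold (6.26 ± 0.22), DAK2 60.0-fold (5.91 ± 0.15) and FDH1, a formate dehydrogenase gene, 37.4-fold (5.22 ± 0.22). The largest falls after TUP1 itself were in MF(ALPHA)2, an alpha-factor gene, at 58.8-fold lower (−5.88 ± 0.14, adjusted p = 1.68e-06), THI22, similar to thiamine synthesis genes (−3.97 ± 0.23), and SRD1 (−3.54 ± 0.34). NDJ1, a meiotic telomere gene, dropped under the floor and was at least 4.67-fold lower. In all, 1255 of 5449 genes passed, 567 higher and 688 lower (n = 2 and 3 arrays). Rises outnumbered falls without wild-type replicate 1 (440 and 385), either ssn6 array (390 and 377) or tup1 replicate 1 (230 and 197).

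Of the genes that changed at least 2-fold in the tup1 deletion, 326 were higher and 282 lower, with 24 rises and 2 falls of 16-fold or more. The majority of rises was not stable, at 205 higher and 117 lower without tup1 replicate 1 and 320 higher and 452 lower without tup1 replicate 2. The risen genes had a median wild-type level of 9.60, and 3 of them were under the floor in wild type. Of 31 lists, 22 passed camera, 17 upward and 5 downward, and 24 passed fry. With an estimated correlation 0 lists passed camera, the lowest adjusted p being 0.122, and 9 lists had an unadjusted p under 0.05.

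Both mating-type programmes shifted in the tup1 deletion. All 7 a-specific genes rose (7 adjusted over the list alone, median 2.67, adjusted p = 3.68e-08, and adjusted p = 0.127 with an estimated correlation), MFA2 by 4.23 ± 0.22 and AGA2 by 4.13 ± 0.19. All 5 alpha-specific genes fell (5 adjusted over the list alone, median −2.69, adjusted p = 1.27e-05, and adjusted p = 0.141 with an estimated correlation). Besides MF(ALPHA)2 these included STE3 (−2.77 ± 0.14), the alpha-factor gene MF(ALPHA)1 (−2.69 ± 0.38) and SAG1, for alpha-agglutinin (−2.66 ± 0.21). Of the 11 haploid genes, 1 rose and 2 fell (1 and 4 adjusted over the list alone, adjusted p = 0.355, or 0.00691 by fry), the falls being STE12, the transcription factor of the mating response, by 1.07 ± 0.19 and GPA1, for the G protein alpha subunit (adjusted p = 0.0032).

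All measured flocculin, DAN and TIR genes and most PAU genes rose in the tup1 deletion too. The 4 flocculin genes all rose (4 adjusted over the list alone, median 3.29, adjusted p = 9.68e-07, and adjusted p = 0.141 with an estimated correlation), FLO1 by 4.50 ± 0.31 and FLO11 by 3.43 ± 0.16. All 6 DAN and TIR genes rose (6 adjusted over the list alone, median 2.18, adjusted p = 4.32e-07, and adjusted p = 0.127 with an estimated correlation), DAN1 by 5.27 ± 0.17. Of 13 PAU genes, 10 rose (11 adjusted over the list alone, median 1.79, adjusted p = 9.56e-09, and adjusted p = 0.127 with an estimated correlation), with PAU24 at 4.99 ± 0.13. PAU4 (0.67 ± 0.24), PAU18 (0.30 ± 0.23) and PAU23 (0.30 ± 0.14) did not pass. Of 8 other oxygen-regulated genes 1 rose (3 higher and 1 lower adjusted over the list alone, adjusted p = 0.355).

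Part of the carbon source genes rose in the tup1 deletion too. Hexose transporter genes gave 6 rises of 14 (8 adjusted over the list alone, median 1.36, adjusted p = 3.4e-05, and adjusted p = 0.143 with an estimated correlation), with HXT10 at 3.91 ± 0.17. Maltose and isomaltase genes gave 8 rises of 9 (8 adjusted over the list alone, median 1.76, adjusted p = 5.87e-08, and adjusted p = 0.122 with an estimated correlation), with IMA1 at 4.01 ± 0.14, and 4 rises without tup1 replicate 1. Of the 17 genes for invertase, gluconeogenesis and the use of ethanol, acetate and glycerol 8 rose (13 adjusted over the list alone, median 1.17, adjusted p = 9.68e-07, and adjusted p = 0.261 with an estimated correlation), with PCK1 at 3.21 ± 0.16 and ADH2 at 2.31 ± 0.19, and 5 rose without tup1 replicate 1. Galactose genes gave 5 rises of 9 (5 adjusted over the list alone, adjusted p = 0.000613, and adjusted p = 0.177 with an estimated correlation), with GAL7 at 1.47 ± 0.20, and 3 without tup1 replicate 1. Fatty acid oxidation genes gave 11 rises of 13 (12 adjusted over the list alone, median 1.83, adjusted p = 6e-08, and adjusted p = 0.217 with an estimated correlation), with CTA1 at 3.15 ± 0.39, and 7 without tup1 replicate 1. Wild-type replicate 3, with the low mean of 9.82 for fatty acid oxidation and 10.82 for the other carbon source list (11.45 and 11.47 in the other wild-type arrays), enters this comparison as well. Among 35 respiratory genes 2 rose (0 adjusted over the list alone, median 0.27, adjusted p = 0.000308, and adjusted p = 0.217 with an estimated correlation). Glycolysis genes gave 1 fall of 15 (1 adjusted over the list alone, adjusted p = 0.405, or 0.0491 by fry) and citric acid cycle genes 1 rise of 11 (1 adjusted over the list alone, adjusted p = 0.0712, or 0.0353 without tup1 replicate 2 and 0.0455 by fry).

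Some sporulation, early meiotic, general stress and damage genes rose in the tup1 deletion, while most members of each list did not pass. Of 16 middle and late sporulation genes 5 rose (5 adjusted over the list alone, adjusted p = 0.000374, and adjusted p = 0.197 with an estimated correlation), DIT1 by 5.71 ± 0.18 and DIT2 by 5.61 ± 0.20. Of 19 early meiotic genes 6 rose (9 adjusted over the list alone, adjusted p = 0.00129, and adjusted p = 0.197 with an estimated correlation), IME1 by 1.97 ± 0.28 and the cohesin gene REC8 by 1.64 ± 0.14. The 6 rises became 3 without wild-type replicate 1 and 2 without tup1 replicate 1. Among 20 stress genes 5 rose and 2 fell (8 and 2 adjusted over the list alone, adjusted p = 0.00154, and adjusted p = 0.197 with an estimated correlation), with the desiccation gene GRE1 at 3.01 ± 0.36 and SSA4 at −1.32 ± 0.13. The 5 rises became 3 without wild-type replicate 1 or either ssn6 array and 2 without tup1 replicate 1, with 1 fall left in each case. In the ribonucleotide reductase and damage list 2 of 5 rose (5 adjusted over the list alone, adjusted p = 0.000308, and adjusted p = 0.143 with an estimated correlation), HUG1 by 3.45 ± 0.22 and RNR3 by 2.23 ± 0.13. Osmotic genes gave 1 rise of 11 (0 adjusted over the list alone, adjusted p = 0.104, or 0.0432 without wild-type replicate 1).

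Repressor genes gave 8 rises and 1 fall of 16 in the tup1 deletion (10 and 1 adjusted over the list alone, adjusted p = 0.000124, and adjusted p = 0.197 with an estimated correlation). CIN5 rose by 2.27 ± 0.20 and YAP6 by 1.89 ± 0.22, and the count was 5 without wild-type replicate 3, either ssn6 array or tup1 replicate 1. Nitrogen-regulated genes gave 10 rises of 20 (11 adjusted over the list alone, adjusted p = 0.000373, and adjusted p = 0.28 with an estimated correlation), with GAP1 at 2.04 ± 0.13, and 3 without tup1 replicate 1. Subtelomeric genes gave 88 rises and 24 falls of 235 (98 and 29 adjusted over the list alone, median 0.40, adjusted p = 8.99e-09, and adjusted p = 0.127 with an estimated correlation), and 51 rises and 10 falls without tup1 replicate 1.

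Of 54 ribosome biogenesis genes, 31 fell in the tup1 deletion. The list had a median of −1.09 (48 adjusted over the list alone, adjusted p = 8.67e-12, and adjusted p = 0.335 with an estimated correlation), such as RPA49, a subunit of RNA polymerase I (−1.87 ± 0.31), and UTP6 of the small-subunit processome (−1.98 ± 0.32). The mean level of this list was 9.67 in tup1 replicate 1 and 10.66 in replicate 2, against 10.71 and 10.69 in ssn6 and 11.12 to 11.39 in wild type. The 17 rRNA control probe sets had a mean of 6.72 on tup1 replicate 1, the lowest of the 7 arrays, and 9.34 on replicate 2, against 8.73 and 7.47 in ssn6 and 11.06, 8.41 and 12.42 in wild type. Leaving out single arrays moved the 31 falls to 10 (tup1 replicate 1), 50 (tup1 replicate 2), 11 (wild-type replicate 1), 19 (wild-type replicate 3) or 18 (either ssn6 array). Ribosomal protein genes gave 5 falls of 128 (0 adjusted over the list alone, median −0.29, adjusted p = 3.26e-05, and adjusted p = 0.64 with an estimated correlation). Their mean was 12.63 in tup1 replicate 1 and 13.15 in replicate 2, and the list did not pass without replicate 1 (median −0.02, adjusted p = 0.742) or by fry (0.17). The 5 falls were 2 without wild-type replicate 1, 1 without wild-type replicate 3 or either ssn6 array, 0 without tup1 replicate 1 and 62 without tup1 replicate 2.

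Some amino acid and phosphate genes fell in the tup1 deletion, fewer of them without tup1 replicate 1. Gcn4-regulated amino acid genes gave 8 falls of 21 (10 adjusted over the list alone, median −0.50, adjusted p = 0.000643, and adjusted p = 0.217 with an estimated correlation), among them the aspartate kinase gene HOM3 (−1.84 ± 0.16) and the arginine synthesis gene ARG4 (−1.20 ± 0.12). That count was 5 without wild-type replicate 1 or either ssn6 array and 3 without tup1 replicate 1. Phosphate genes gave 7 falls of 10 (7 adjusted over the list alone, median −0.73, adjusted p = 0.000987, and adjusted p = 0.197 with an estimated correlation), 3 without wild-type replicate 1 and 1 without tup1 replicate 1. The acid phosphatase gene PHO5 read −1.35 ± 0.28 (adjusted p = 0.0167; up to 0.131 over the alternatives). Iron genes gave 2 rises and 3 falls of 16 (2 and 5 adjusted over the list alone, adjusted p = 0.67), with the reductase gene FRE1 at −1.30 ± 0.16. The 3 falls were 1 without wild-type replicate 1, either ssn6 array or tup1 replicate 2, and 5 without wild-type replicate 2. Histone genes gave 0 changes of 8 (0 adjusted over the list alone, adjusted p = 0.442) and COS genes 1 fall of 8 (1 adjusted over the list alone, adjusted p = 0.72).

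The number of genes called in the tup1 deletion depended on the arrays used. Among fits with 1 array left out it was lowest without tup1 replicate 1, and it was 825 without wild-type replicate 1. With only the genotypes compared it was 767. Leaving out either ssn6 array is that same fit, since a lone ssn6 array adds no spread to the shared error. At an adjusted p of 0.01, 456 genes passed, 375 of them at least 2-fold.

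**Figure D2:**
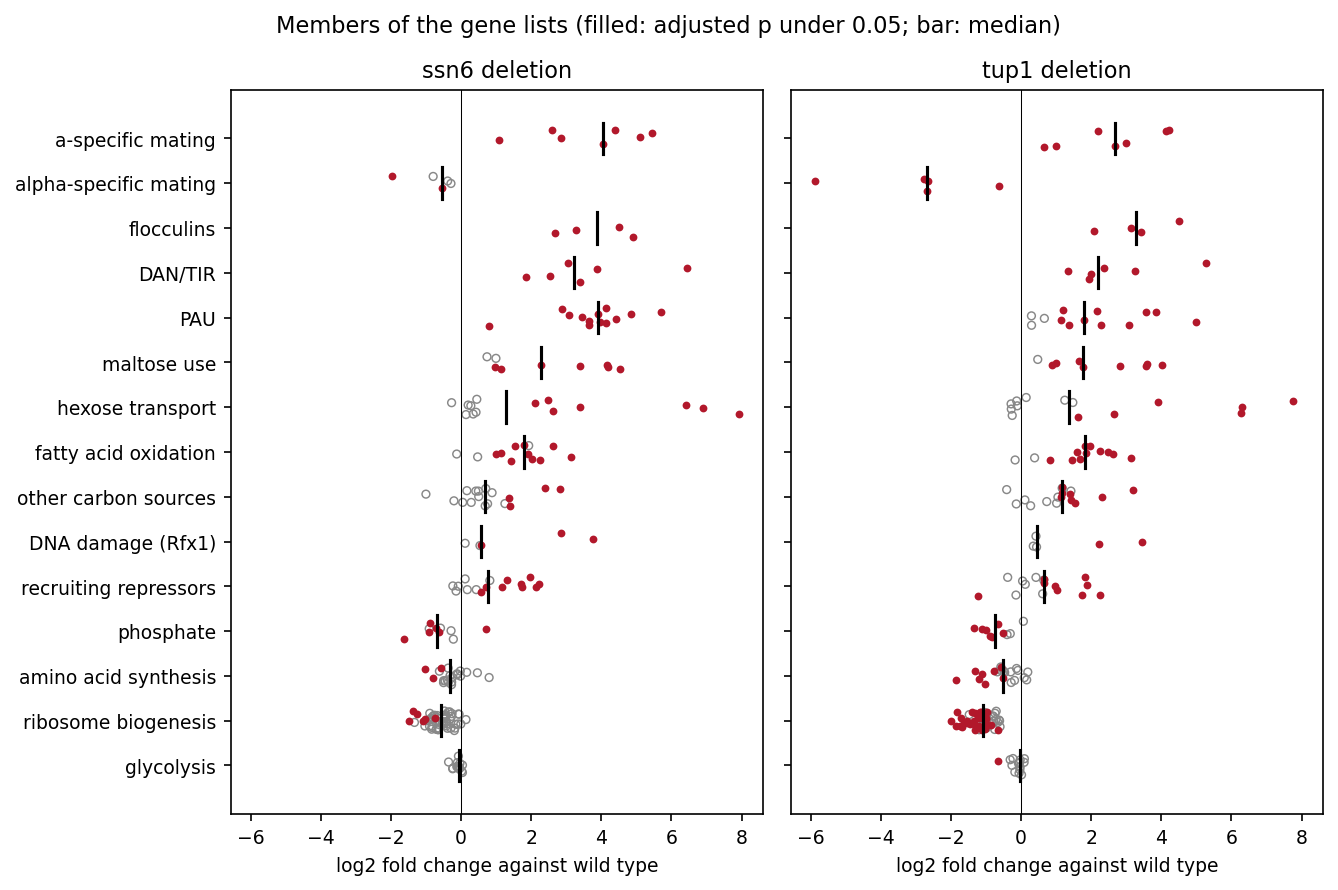
Log2 fold change against wild type of the members of each gene list in the ssn6 and the tup1 deletion; points are genes, filled where the gene passed an adjusted p of 0.05, and a bar marks the median of the list. The a-specific, PAU, DAN/TIR, flocculin and maltose lists lie to the right in both deletions, and the alpha-specific list lies farther to the left in tup1 (median −2.69) than in ssn6 (−0.55).

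The next question was how far the changes of the deletions coincide. Together 363 genes were higher in both and 274 lower in both, 637 genes in all, while 6 went in opposite directions. Independent lists of these sizes would share 52.0 higher and 70.6 lower genes and 121 in opposite directions. Simulated unchanged groups, with their drawn wild-type arrays in common, yield hardly any calls and shared 0. They do not measure what the shared controls add to these counts. HXT13, HXT17, DAK2, DIT1, DIT2, DAN1 and PAU24 were among the 12 largest rises in each deletion, and ARO10 was among the 8 largest falls in each. Of 414 genes at least 2-fold higher in either deletion, 238 were so in both (19.5 for independent lists), and 51 differed between the deletions. Of 358 genes at least 2-fold lower in either, 62 were so in both (7.14 for independent lists), and 37 differed.

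Across genes the fold changes of the deletions had a Pearson correlation of 0.817, against 0.401 for simulated unchanged groups, and a covariance of 0.515, against 0.0195; genes are not independent replicates. The difference in covariance, 0.495, estimates the shared effect if all genotypes vary alike. Pairs of wild-type arrays differed by more (standard deviation 0.367 to 0.498) than the ssn6 pair (0.197), so the simulated covariance may be too low. Part of the excess in shared calls may come from the common controls. The 3 wild-type arrays cannot give 2 to each deletion, and no fit with separate controls was run. The count of 637 shared genes was 237 without ssn6 replicate 1, 223 without ssn6 replicate 2 and 346 without tup1 replicate 1, and 258 at an adjusted p of 0.01.

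The genes with opposite changes were few and include a cell wall and a mating gene. They were picked out after their values were seen. THI22 rose by 1.68 in ssn6 and stood at −3.97 in tup1, UTR2, a chitin transglycosylase gene of the cell wall, at 0.66 and −2.11, and PRM1, a membrane protein gene of mating cell fusion, at 1.40 and −0.86. The remaining ones were ECM22, a sterol regulator gene (0.61 and −0.61), FLO8, an activator gene of flocculation (0.73 and −0.62), and the Ty element gene YGR109W-B (1.42 and −0.79). Their adjusted p values between the deletions, from 0.000101 for THI22 to 0.0187 for ECM22, follow from this choice and are no separate evidence.

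In the direct test between the deletions, fewer genes passed than in either comparison with wild type. MF(ALPHA)2 was 40.0-fold higher in ssn6 than in tup1 (log2 difference 5.32 ± 0.15, adjusted p = 1.58e-05), THI22 50.4-fold (5.66 ± 0.26) and UTR2 6.85-fold (2.78 ± 0.15). The deleted genes differed as well, TUP1 at least 79.4-fold higher in ssn6 and CYC8 50.4-fold higher in tup1. In all, 131 genes passed, 104 higher in ssn6 and 27 higher in tup1, 98 of them at least 2-fold (84 and 14; n = 2 and 2 arrays).

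By camera 11 lists stood higher in ssn6 than in tup1 and 0 lower, and 6 lists passed fry. With an estimated correlation 0 passed camera, the lowest adjusted p being 0.168, and 4 lists had an unadjusted p under 0.05. PAU genes differed by a median of 1.65, with 6 of 13 past the threshold (12 adjusted over the list alone, adjusted p = 1.77e-13, and adjusted p = 0.168 with an estimated correlation). That count was 3 without ssn6 replicate 1 and 0 without ssn6 replicate 2. With array weights 11 of the 13 PAU genes passed, and 10 with eBayes trend and robust settings. PAU17 differed by 1.94 ± 0.14 and PAU18 by 2.59 ± 0.25. The a-specific list differed by a median of 1.22, with 2 of 7 past the threshold (6 adjusted over the list alone, adjusted p = 4.96e-07, and adjusted p = 0.168 with an estimated correlation), BAR1, the protease that degrades alpha-factor, by 1.93 ± 0.16 and STE2 by 1.38 ± 0.20. The alpha-specific list differed by 1.89, with 2 of 5 past the threshold (4 adjusted over the list alone, adjusted p = 4.03e-07, and adjusted p = 0.168 with an estimated correlation), MF(ALPHA)2 and SAG1 (2.28 ± 0.24). DAN and TIR genes differed by 0.82, 1 of 6 past the threshold (3 adjusted over the list alone, adjusted p = 0.000238, and adjusted p = 0.168 with an estimated correlation), DAN1 by 1.16 ± 0.19.

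The other lists that separated the deletions did so by less. Ribosome biogenesis genes stood higher in ssn6 by a median of 0.55 with 1 of 54 past the threshold (0 adjusted over the list alone, adjusted p = 5.61e-09, and adjusted p = 0.612 with an estimated correlation), and ribosomal protein genes by 0.23 with 0 of 128 (0 adjusted over the list alone, adjusted p = 3.6e-09, and adjusted p = 0.665 with an estimated correlation). Without tup1 replicate 1, whose levels of both lists and of the rRNA controls (6.72) were the lowest of the 7 arrays, neither passed (medians −0.02 and −0.02, adjusted p = 0.476 and 0.594). Gcn4-regulated genes differed by 0.27 with 1 of 21 past the threshold (2 adjusted over the list alone, adjusted p = 0.00144, and adjusted p = 0.457 with an estimated correlation). Subtelomeric genes differed by 0.15, with 9 of 235 higher in ssn6 and 2 lower (23 and 7 adjusted over the list alone, 25 and 5 with array weights, 16 and 5 with the replicate number crossed, adjusted p = 0.00462, and adjusted p = 0.457 with an estimated correlation). Those 9 were 14 without wild-type replicate 2, 2 without ssn6 replicate 1, 0 without ssn6 replicate 2 and 4 without tup1 replicate 1, the 2 lower ones were 0 in these last 3 cases, and the list missed the threshold without tup1 replicate 2 (adjusted p = 0.0696). Flocculin genes differed by 0.36, 1 of 4 past the threshold (2 adjusted over the list alone, adjusted p = 0.0258, and adjusted p = 0.525 with an estimated correlation), and missed it without tup1 replicate 1 (0.0502), with FLO11 at 1.48 ± 0.18. Maltose genes differed by 0.53 with 0 of 9 past the threshold (2 adjusted over the list alone, adjusted p = 0.0276, and adjusted p = 0.286 with an estimated correlation), and missed it without ssn6 replicate 2 (0.0789) or tup1 replicate 2 (0.0504). Haploid genes differed by 0.29 with 2 of 11 past the threshold (3 adjusted over the list alone, adjusted p = 0.0301, and adjusted p = 0.286 with an estimated correlation), and missed it without tup1 replicate 2 (0.0683). By fry the ribosome biogenesis (0.367), ribosomal protein (0.367), Gcn4 (0.129), subtelomeric (0.162), flocculin (0.136) and maltose lists (0.0839) did not separate the deletions. Without wild-type replicate 2 and tup1 replicate 1 together, the Gcn4 (0.0555), flocculin (0.121), maltose (0.0555) and haploid lists (0.0555) and both ribosome lists (0.53 and 0.523) did not pass.

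For hexose transporter (median difference 0.46, adjusted p = 0.0817, or 0.0391 with only the genotypes compared), fatty acid oxidation (−0.03, 0.907), repressor (0.15, 0.197), nitrogen (−0.19, 0.361) and phosphate genes (0.02, 0.599), no difference between the deletions passed in the reported fit, which does not show that the deletions act alike on them. The other carbon source list leaned toward tup1 (−0.23, adjusted p = 0.105) and passed without wild-type replicate 3 (0.0235) or tup1 replicate 2 (0.0289) and with the replicate number as a block (0.0228). Iron genes (0.03, 0.0573) passed without ssn6 replicate 2 (0.0372) or tup1 replicate 1 (0.00171), and histone genes (−0.19, 0.0817) without tup1 replicate 1 (0.0237) or by fry (0.0201).

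The count of 131 genes was the least stable one, at 62 without wild-type replicate 1, 257 without wild-type replicate 2, 13 without ssn6 replicate 1, 5 without ssn6 replicate 2 and 30 without tup1 replicate 1. It was 58 with the replicate number as a block, 412 with array weights and 25 at an adjusted p of 0.01.

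**Figure D3:**
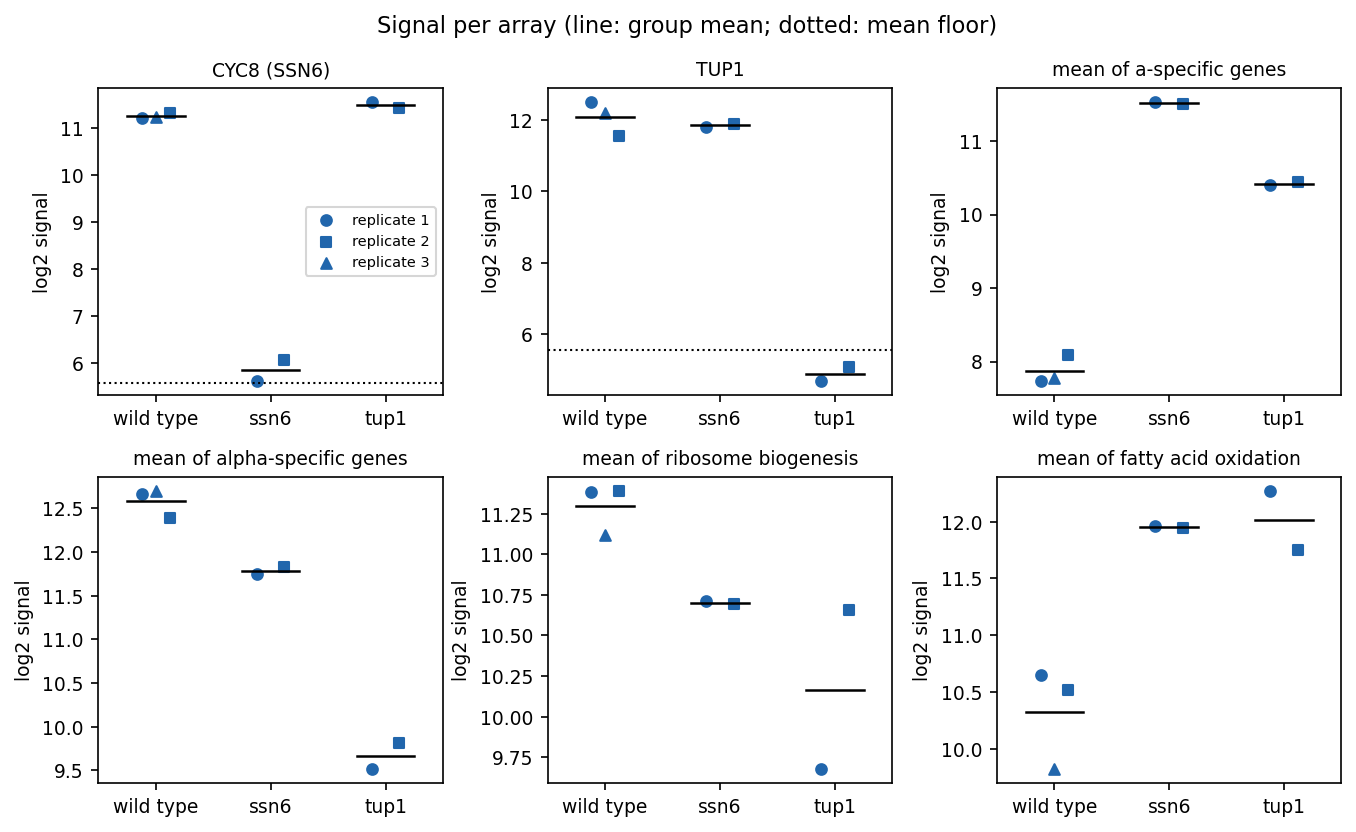
Log2 level on each of the 7 arrays of CYC8, TUP1 and the means of selected gene lists; one symbol per array, shaped by replicate, with a line at the mean of each genotype and a dotted line at the mean floor. CYC8 is low on both ssn6 arrays (5.62 and 6.07), TUP1 on both tup1 arrays (4.69 and 5.07), and ribosome biogenesis is lowest on tup1 replicate 1 (9.67).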

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

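The tests on the mating genes, on the reporter probe sets and on the ribosome genes were all chosen after the result was seen, and genes without a list below were picked by size of change or by opposite signs. The direct test between the deletions singled out 11 lists by camera at its preset correlation, 6 by fry and 0 by camera with an estimated correlation (lowest adjusted p = 0.168, with 4 lists at an unadjusted p under 0.05), and the following genes. The median difference, ssn6 minus tup1, was 1.22 for a-specific, 1.89 for alpha-specific, 0.29 for haploid, 0.53 for maltose, 0.36 for flocculin, 0.82 for DAN and TIR, 1.65 for PAU, 0.27 for Gcn4-regulated, 0.23 for ribosomal protein, 0.55 for ribosome biogenesis and 0.15 for subtelomeric genes.

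Genes higher in ssn6 than in tup1 by this test included THI22 (5.66), MF(ALPHA)2 (5.32), PAU4 (2.99), SRD1 (2.90), UTR2 (2.78), PAU14 (2.77) and PAU8 (2.76), where PAU genes can share probes. PAU4 and PAU14 missed the threshold without ssn6 replicate 2 (adjusted p = 0.0548 for both). SRD1 and PAU8 missed it without either ssn6 array (up to 0.137 and 0.121). Genes higher in tup1 were YDR034C-A (−3.03), ANS1 (−2.53), YEL073C (−2.44), YMR175W-A (−2.14), PAI3, an inhibitor of proteinase A (−1.86), DSE1, a daughter cell gene (−1.62), and YOR376W-A (−1.56). These 7 missed the threshold without one or both ssn6 arrays, with highest adjusted p values of 0.0548 for YDR034C-A, 0.0835 for ANS1, 0.121 for YEL073C, 0.112 for YMR175W-A, 0.135 for PAI3, 0.191 for DSE1 and 0.112 for YOR376W-A. The genes with opposite changes differed by 1.22 (ECM22), 2.21 (YGR109W-B), 2.26 (PRM1) and 1.35 (FLO8), beside THI22 and UTR2.

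The alpha-specific genes stood lower in tup1 than in ssn6. A share of cells of mating type a in the tup1 cultures would lower the alpha regulator gene HMLALPHA1 as far as its targets, but it changed by −0.84 ± 0.19 (adjusted p = 0.0222), against a median of −2.69 for the list. It would also lower the listed genes alike, but MF(ALPHA)2 fell by 5.88 ± 0.14 and AFB1 by 0.63 ± 0.19. Such cells would raise the a-specific genes, which did rise in tup1 (median 2.67), so that list does not decide. A single outlying tup1 array is argued against by a gap of 1.93 between the lowest ssn6 and the highest tup1 mean of the list.

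Probe sets labelled as reporters on the array, which are not part of the reported comparisons, changed in both deletions. The label does not say whether a sequence is foreign to yeast, and their identity was not looked up. One was under the floor on all wild-type arrays (4.26) and read 13.85 in ssn6 and 13.83 in tup1, so it was at least 309-fold and 305-fold higher (9.59 and 9.57 apart in measured means, which the floor makes inexact). Whether it matches a marker or deletion cassette carried by both strains is not given in the sources used here, so its values are not read as a change in expression of a yeast gene. Another rose by 1.46 and 1.18. In tup1 3 further ones rose by 0.64, 0.96 and 0.70, and in ssn6, where these 3 were under the floor, they were at least 154-fold, 157-fold and 137-fold lower. Among 3470 unnamed probe sets, 396 lay above the floor, and 16 of them were higher and 10 lower in ssn6, and 38 higher and 20 lower in tup1. One fission yeast probe set of 1746 rose in ssn6, by 0.73, and 0 did in tup1 by limma.

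In all, 6 reporter probe sets fell in ssn6 and lay under the floor on both of its arrays, which makes them lower by at least 1.66-fold (this one under the floor on 1 wild-type array too) to at least 157-fold. Weak hybridisation of those arrays is argued against by the hybridisation controls (ssn6 mean 10.48). They read 10.26 on ssn6 replicate 1, within the 9.88 to 10.44 of the other arrays, and 10.71 on replicate 2, above it. Loss of the corepressor as such is argued against by the tup1 deletion, where these probe sets had a median change of 0.67, with 3 higher and 0 lower. The 6 probe sets are not all separate sequences: several, among them the 3 that rose in tup1, carry the name of one sequence. These 3 had mean levels of 12.85, 12.88 and 12.68 in wild type and 13.50, 13.85 and 13.39 in tup1. A matching sequence thus gave strong signal in both, and it need not be a foreign reporter. A sequence that the ssn6 strain lacks could give the pattern, but that all 6 were under the floor is part of the pattern and no separate evidence. The strain cannot be told apart from the deletion, since each ssn6 array carries both.

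Ribosome genes stood lower in tup1 than in ssn6, and tup1 replicate 1 alone may account for this, since without it neither ribosome list passed (lower adjusted p = 0.476; medians −0.02 and −0.02), while without tup1 replicate 2 the medians were 1.06 for biogenesis and 0.49 for ribosomal proteins. The lower level of ribosome biogenesis genes in tup1 than in wild type (median −1.09, adjusted p = 8.67e-12, and adjusted p = 0.335 with an estimated correlation) rested on that array in part. Without tup1 replicate 1 the list still passed at the preset correlation (adjusted p = 1.01e-09), with a smaller median of −0.60 and 10 falls in place of 31. Without wild-type replicate 2, the array with the large actin 3' to 5' difference, the median was −1.06 (adjusted p = 2.66e-09). RNA composition, with rRNA controls lowest on tup1 replicate 1 (6.72), and growth state at harvest were not tested as causes and stay open.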

How the results depend on the processing

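The tests without wild-type replicate 2 and tup1 replicate 1 together, and with crossed replicate numbers, were chosen after seeing the data. Of 93 gene list results, each run under 18 or 19 alternatives, 0 reversed, and of 229 named gene results, each run under 16 or 17, 0 reversed. A list counted as reversed only if it passed in both settings with opposite directions. A change of direction in a list that did not pass, such as ribosomal proteins in ssn6 between camera and fry, was not counted. Most named genes were picked for large changes in these same arrays, so their 0 is little evidence of stability. List results kept their side of the threshold 1648 times, gained it 21 times and lost it 95 times, 54 of them with camera's estimated correlation. Named gene results did so 3543, 1 and 344 times. Per array, 36 to 70 genes lay under the floor.

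At an adjusted p of 0.01, a stricter limit by construction, 397 genes passed in ssn6, 456 in tup1 (375 at least 2-fold), 258 in both and 25 between the deletions. With array weights, 2139 passed in ssn6 and 412 between the deletions; the ssn6 arrays got weights of 3.65 and wild-type replicate 2 got 0.286. With only the genotypes compared in the fit, 767 passed in tup1. Without wild-type replicate 2 and tup1 replicate 1, 830 passed in tup1, 75 between the deletions, and 6 lists differed between them. With an estimated correlation in camera, 0 lists passed in ssn6, 0 in tup1 and 0 between the deletions; with fry, 6 lists differed between the deletions. Apart from the stricter limit, the cause was not tested.

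Leaving out 1 array at a time gave 279 to 1196 genes in ssn6, 427 to 1366 in tup1 and 5 to 257 between the deletions. At least 2-fold, the range was 274 to 469 in ssn6 and 322 to 772 in tup1, and 223 to 729 genes changed in both. A lone remaining array was taken to vary like the other groups. For tup1 against wild type, leaving out either ssn6 array gives the fit with only the genotypes compared. The same holds for ssn6 against wild type and either tup1 array. Such values come from 1 refit and are no separate tests of single arrays.

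With the replicate number as a block (replicate block), 58 genes passed between the deletions, 708 in ssn6 and 838 in tup1. The numbers as labelled do not pair all genotypes alike. Differences between replicates 1 and 2 correlated at −0.35 for wild type with ssn6, 0.25 for wild type with tup1 and −0.27 for ssn6 with tup1. With the ssn6 numbers crossed, 1199, 1298 and 173 genes passed in ssn6, in tup1 and between the deletions, against 1059, 1255 and 131 without a block. A factor shared by arrays of different genotypes is therefore not excluded.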

Other observations

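The gene groups in the first paragraph and their tests were chosen after the values were seen; the tests on neighbouring genes were chosen before. Of 17 genes of the pheromone response, 5 were lower in tup1 and the other 12 did not pass, with no test of the group as a whole. Among the 5 were the fusion gene FUS1 (−2.31 ± 0.22) and SST2, which dampens the response (−2.45 ± 0.17). In ssn6 4 rose, 2 fell and 11 did not pass, and 7 were higher in ssn6 than in tup1. Of 13 thiamine genes, 9 rose in ssn6 and 7 in tup1, such as THI4 (1.94 ± 0.23 and 1.85 ± 0.23) and the regulator gene THI2 (2.15 ± 0.17 and 1.67 ± 0.17), with THI22 the one that fell in tup1. Of 9 genes of daughter cell separation, 5 fell and 2 rose in ssn6, against 1 and 1 in tup1, with EGT2 at −0.77 ± 0.12 and DSE1 at −1.57 ± 0.21 in ssn6, and 2 were lower in ssn6 than in tup1. Of 6 genes of aromatic amino acid breakdown, 3 rose and 2 fell in ssn6, and 2 rose and 2 fell in tup1. The falls were in ARO10 and ARO9 (−2.22 ± 0.19 in ssn6 and −1.12 ± 0.19 in tup1). The rises were in ESBP6 (0.98 ± 0.19 and 1.17 ± 0.19), the decarboxylase gene PDC6 (1.47 ± 0.16 and 1.90 ± 0.16) and, in ssn6, PDC5 (1.65 ± 0.20). Of 8 zinc genes, 1 rose and 1 fell in ssn6, and 1 rose and 2 fell in tup1. ZPS1 rose (2.52 ± 0.15 and 2.18 ± 0.15), IZH2 fell (−1.25 ± 0.18 in both), and the transporter gene ZRT1 fell in tup1 (−0.93 ± 0.21) and was 1.63 ± 0.23 higher in ssn6 than in tup1.

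Genes that rose at least 2-fold in both deletions often lay side by side. Among 5017 neighbouring pairs, with 235 risen genes, both members rose in 49, against 9.44 when the genes were shuffled (one-sided permutation p = 1e-05, the smallest that 100000 shuffles can give). Examples are DIT1 with DIT2, HXT17 with YNR071C, and TIR2 with TIR4. The excess held for divergent (17 against 2.42), tandem (22 against 4.51) and convergent pairs (10 against 2.51), with a highest one-sided permutation p of 3e-04. A spread of the rise to neighbours of any orientation predicted this excess. Shuffling places the risen genes at random, however, so neighbouring genes that each rise on their own would give an excess too. The test cannot tell these apart. Clusters among the 10 outermost genes of each chromosome arm do not account for all of the excess. Without these genes 21 such pairs were left, against 5.40 when shuffled (permutation p = 1e-05). Clusters that lie further in than this cut were kept, so the test does not decide on subtelomeric clusters in a wider sense. Whether a shared promoter region adds to the excess stays open: both members rose in 17 of 87 divergent pairs with a risen gene and in 32 of 282 others, an odds ratio of 1.89 (95% interval 0.929 to 3.76; two-sided Fisher's exact p = 0.0691). Duplicated genes that lie side by side and share probes were not separated from the rest.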
